A study of Homo sapiens with 11 samples.

How the data were processed

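Expression was measured on 11 GeneChip Human Gene 2.1 ST arrays hybridised with labelled total RNA of MDA-MB-468 breast cancer cells. Cells had been treated for 24 h with tumour necrosis factor (TNF) at 40 ng/ml, with apigenin at 40 µM, with both, or with neither, and RNA had been purified with TRIzol and chloroform. Groups were taken from the sample titles: 3 control arrays, 3 TNF arrays, 2 apigenin arrays (replicates 1 and 2) and 3 arrays of TNF plus apigenin. The titles speak of triplicates, and the sources used here do not say why apigenin has 2 arrays, or whether 1 was left out for its quality. The replicate numbers do not say whether cultures were grown and treated separately. All p-values therefore measure only the spread between these arrays, which may be technical.

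The values analysed were the deposited log2 values of 53617 probe sets, made by the authors with Affymetrix Expression Console per the submitters' processing notes. Its version, the summarisation algorithm and the annotation build are not given in the sources used here. The base of the logarithm was inferred from the range of the values, 0.38 to 12.31, which is that of log2 probe set summaries and not of linear intensities. No detection calls were used here, and scanned images and cell-level intensities were not analysed here. Whether the values had been normalized across all arrays is not stated, and array apigenin 1 had a narrower distribution than the rest. The number of arrays limits the precision.

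Probe sets were paired with genes through a table of the array's probe sets. It listed 25713 of them, 23871 with 1 gene symbol and 1842 with several, and gave no symbol for the other 27904. Of the probe sets with 1 symbol, 22569 matched a RefSeq gene (assembly GRCh38.p14, used for names only) by gene number, and 90 symbols were brought up to date. This gave 22395 genes with a probe set of their own. For the 632 genes with several probe sets, the probe set with the highest mean over all arrays was used. A gene was tested if at least 2 arrays lay at or above the median of the probe set means (2.53), whatever their group, which left 15865 genes.

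A linear model with 1 mean per group was fitted to all 11 arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with default settings, 7 residual degrees of freedom). P-values were two-sided, adjusted by the Benjamini-Hochberg method over all genes tested, and called at an adjusted p under 0.05. The 5 group comparisons were TNF against control, apigenin against control, TNF plus apigenin against TNF, TNF plus apigenin against control, and TNF plus apigenin against apigenin. The interaction was the TNF effect with apigenin minus the TNF effect without it. Errors given with log2 changes are the moderated standard errors of limma (SE), intervals are 95%, and errors given with group means are standard deviations (SD). The deposited values were not rescaled. Slopes through the origin and Pearson correlations were taken across genes between effects estimated from separate arrays, without a p-value. A Pearson correlation was also taken between the TNF effect and TNF plus apigenin against TNF, which share the TNF arrays, and set against simulated unchanged groups.

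A set of 30 gene lists, the comparisons, the named genes and the alternatives were fixed before the data were examined. The lists held NF-kB targets and feedback inhibitors, chemokines, inflammatory cytokines and growth factors, NF-kB pathway kinases and TNF receptor proximal components, interferon-stimulated genes, antigen presentation, death receptor and apoptosis genes, G1/S and DNA replication genes, G2/M and mitosis genes and replication-dependent histones. They also held growth arrest and p53-responsive genes, aryl hydrocarbon receptor targets, NRF2 antioxidant genes, ATF4 and unfolded protein response genes, cholesterol and fatty acid synthesis, hypoxia and glycolysis, heat shock, EGFR and MAPK feedback, FOXO-responsive genes, mesenchymal and matrix remodelling genes, epithelial adhesion and basal and squamous genes. The rest were long non-coding RNA genes, transporters and phase II enzymes, mitochondrially encoded genes, ribosomal protein genes, and markers of macrophages, of T and B cells, of fibroblasts and of endothelium.

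Each list with at least 5 tested genes was tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera compares the genes of a list with all other genes. Camera with an estimated correlation was run beside it, as was fry, which asks whether the genes of a list move on balance to either side or change in either direction without reference to other genes. Members past the threshold were counted over all genes and adjusted over the list alone.

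Genes were named by a rule. For TNF against control, apigenin against control and TNF plus apigenin against TNF it took the 10 highest and the 10 lowest log2 changes among called genes whose groups of arrays did not overlap. For the other comparisons and the interaction it took the 5 highest and the 5 lowest called. Probe sets without a name, uncharacterised loci, pseudogenes and small RNAs were passed over. From each list that camera called, or with at least 3 called members, up to 4 members with the largest absolute change were added. CCL2, CXCL8, IL6, IL1A, CSF2, IKBKE, TNFAIP3, ICAM1, CYP1A1 and CYP1B1 were named whether called or not. IL6 and IL1A fell below the filter, and CSF2 had no probe set of its own among those used here. Other genes named in the text were chosen after their values were seen.

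The model was tested on simulated data with 15865 genes and the group sizes and spread of these arrays. At a true change of 1 on the log2 scale it recovered 78% of changed genes in TNF against control, 48% in apigenin against control, 82% in TNF plus apigenin against TNF, 78% in TNF plus apigenin against control, 76% in TNF plus apigenin against apigenin and 20% in the interaction. At a true change of 2 the interaction recovered 90% and the other comparisons 100%. Camera called a shifted simulated list (adjusted p = 2.96e-24) and called 0 of 20 unshifted ones. The simulated genes varied independently of each other, so this is no test of the preset correlation of 0.01. In the real data the estimated correlation was 0.63 for the G2/M and mitosis list, for example.

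Alternatives changed the filter (none, the mean over all arrays, or the 75th percentile at 4.06), the probe sets (mean of a gene's probe sets, or all probe sets without collapse), the scaling (quantile normalization, or a shift of each array to the same median), the fit (trend and robust prior, array weights, replicate number as a block, only the groups compared) and the threshold (adjusted p of 0.01, or an absolute log2 change of at least 1). Each array was also left out in turn. In a group comparison, a fit without an array of another group changes only the spread that the groups share. Lost calls counted out of 11 fits therefore understate the share of the compared arrays on which a call rests. Leaving out an apigenin array leaves that group with 1 array, whose spread is then assumed to equal that of the other groups. After the data had been seen, arrays control 2 and apigenin 1 were left out together, and slopes were also taken over the genes called in the other comparison.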

Results

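MDA-MB-468 is a triple-negative human breast cancer line from a pleural effusion. Its cells were exposed for 24 h to TNF (40 ng/ml), an inflammatory cytokine that signals through NF-kB, to apigenin (40 µM), a flavone of plants such as parsley and celery, to both, or to neither. The series asks what TNF changes in these cells and what apigenin changes of that. The arrays measure messenger RNA and long non-coding RNA, and 15865 genes were tested on 3 control, 3 TNF, 2 apigenin and 3 TNF plus apigenin arrays. Correlations between arrays of a group lay between 0.969, in apigenin, and 0.987, in control and in TNF plus apigenin. The median over all probe sets was 2.53 on the log2 scale, and a gene whose mean in either group lies near it is close to background there. Its change then depends on that background, so it is given on the log2 scale without a fold and is not ranked.

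Array apigenin 1 stood apart. Its median over the tested genes was 3.89 with an interquartile range of 2.4, against 4.16 and 2.7 on apigenin 2 and 4.3 and 2.9 on control 1. Control 2 (4.11 and 2.66) and TNF plus apigenin 3 (4.08 and 2.63) were the next lowest. The median change over all genes was -0.177 for apigenin against control, 0.162 for TNF plus apigenin against apigenin and 0.226 for the interaction, and in these comparisons most list medians are also given relative to that shift. For the others it was between -0.043 and 0.015. All genes called in the 5 group comparisons had groups of arrays that did not overlap. Chance alone gives this for 10% of genes with 3 arrays against 3 and for 20% with 3 against 2. A low p-value with so few arrays all but requires it, so it is no separate support for the calls.

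TNF alone raised CCL2, CXCL10, CXCL8 and TNFAIP3. CCL2, which encodes a chemokine that attracts monocytes, went from 2.51 ± 0.64 (SD, n = 3) in control to 8.39 ± 0.28 with TNF, a rise of 5.88 ± 0.29 on the log2 scale from a control mean at background (adjusted p = 2.79e-08). CXCL10, a chemokine for T cells, rose from 2.42 ± 0.21 to 7.33 ± 0.2, by 4.92 ± 0.18, also from background (adjusted p = 8.68e-10). CXCL8, the neutrophil chemokine interleukin 8, rose from 3.15 ± 0.44 to 7.86 ± 0.06, by 4.7 ± 0.24 or 26.1-fold (adjusted p = 2.95e-08). TNFAIP3, which encodes the NF-kB inhibitor A20, rose 10.5-fold, by 3.39 ± 0.19 (adjusted p = 1.1e-07). Other genes that rose were KMO, an enzyme of tryptophan breakdown, at 8.41-fold, IGFL1 by 2.91 on the log2 scale, PGLYRP4, a receptor for bacterial peptidoglycan, at 6.38-fold, IL22RA2, a soluble decoy receptor for interleukin 22, at 6.07-fold, complement component C3 at 6.02-fold, and CCL20 by 2.52 on the log2 scale.

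Genes lowered by TNF included SPDEF, SCGB2A2 and CLCA2. SPDEF, a transcription factor of luminal and secretory cells, fell by 1.56 on the log2 scale (SE 0.2, adjusted p = 0.000499), and SCGB2A2, which encodes mammaglobin A, fell by 1.61 (SE 0.22, adjusted p = 0.00108). CLCA2, a regulator of chloride currents, fell by 1.77 (SE 0.18, adjusted p = 7.21e-05), from 6.81 ± 0.08 to 5.03 ± 0.2 (SD, n = 3 each; limma). CYP4Z1, a cytochrome P450 of breast tissue, fell by 1.75, CRISP3 by 1.57, the keratin gene KRT4 by 1.48, RASA4B by 1.46, the aminopeptidase gene ANPEP by 1.35, TF, which encodes transferrin, by 1.33 and STAC2 by 1.3. The calls of RASA4B, CYP4Z1 and ANPEP were lost in 7, 5 and 3 of the 11 fits that left out an array.

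Of the 27 NF-kB targets and feedback inhibitors tested, 5 rose with TNF and 22 did not pass the test over all genes; adjusted over the list alone, 13 rose. Besides TNFAIP3 these were TNFAIP2, which rose by 2.05 ± 0.2, TNF itself by 1.79 ± 0.2, the adhesion receptor gene ICAM1 by 1.67 ± 0.21 and NFKBIA, the gene of IkB alpha, by 1.4 ± 0.2. Camera placed the list above all other genes (adjusted p = 2.7e-21; adjusted p = 0.12 with an estimated correlation). Of 17 chemokines, CCL2, CXCL10, CXCL8 and CCL20 rose and CXCL17 fell by 1.11 (SE 0.19, a call lost in 3 of the 11 fits that left out an array), and 8 rose and 1 fell adjusted over the list alone. Camera called this list higher (adjusted p = 5.5e-14), and it was the only list call in any comparison that held with an estimated correlation (adjusted p = 0.035). Among 21 NF-kB pathway kinases and TNF receptor proximal components, IKBKE, the gene of IKK epsilon, rose 3.57-fold, by 1.84 ± 0.19 (adjusted p = 8.54e-05), and the other 20 did not pass. Adjusted over the list alone 4 rose (camera adjusted p = 0.021; adjusted p = 0.71 with an estimated correlation). Of 16 inflammatory cytokines and growth factors, TNFSF15 rose by 1.31 ± 0.2 and 15 did not pass, among them LIF at 1 ± 0.23 (adjusted p = 0.0675) and CSF1 at 0.84 ± 0.19 (adjusted p = 0.0553). Adjusted over the list alone 3 of them rose (camera adjusted p = 0.0065; adjusted p = 0.16 with an estimated correlation).

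TNF also raised 4 matrix remodelling genes and 3 interferon-stimulated genes. Of 23 mesenchymal and matrix remodelling genes tested, 10 rose adjusted over the list alone. The 4 were TNC, which encodes the matrix protein tenascin C (1.91 ± 0.21), the matrix metalloproteinase genes MMP7 (1.73 ± 0.17) and MMP13 (1.64 ± 0.17), and the integrin gene ITGA5 (0.88 ± 0.18, a call lost in 8 of the 11 fits that left out an array). MMP13 had a mean of 1.72 in control, below the median of the probe sets. Camera called the list higher (adjusted p = 5.1e-13; adjusted p = 0.22 with an estimated correlation). Of 38 interferon-stimulated genes, GBP1 rose by 1.7 ± 0.26, IFI44L by 1.16 ± 0.21 and RIGI, an RNA sensor, by 1.09 ± 0.21, and 35 did not pass; adjusted over the list alone 7 rose (camera adjusted p = 1.9e-07; adjusted p = 0.22 with an estimated correlation). The calls of IFI44L and RIGI were each lost in 4 fits with an array left out. Of 8 transporters and phase II enzymes, the sugar transporter gene SLC2A12 rose by 1.35 ± 0.16, also when adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.069 after quantile normalization; adjusted p = 0.42 with an estimated correlation).

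Among 20 antigen presentation genes limma called 0 and 4 lay above control at an unadjusted p under 0.05, with TAP1 at 0.71 ± 0.18 (adjusted p = 0.12). Adjusted over the list alone 1 rose (camera adjusted p = 0.0066; adjusted p = 0.71 with an estimated correlation). Of 10 replication-dependent histone genes limma called 0, and 3 lay below control at an unadjusted p under 0.05. Their median change was -0.5 (camera adjusted p = 0.0017; adjusted p = 0.29 with an estimated correlation). Of 14 basal and squamous genes limma called 0 over all genes and 2 as lower adjusted over the list alone, and 4 lay below control at an unadjusted p under 0.05. Their median change was -0.25 (camera adjusted p = 0.042; adjusted p = 0.069 after quantile normalization; adjusted p = 0.71 with an estimated correlation). CYP1A1 changed by 0.28 ± 0.23 (adjusted p = 0.892) and CYP1B1 by 0.05 ± 0.16 (adjusted p = 0.99).

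In all, TNF against control gave 75 genes higher and 36 lower by limma, out of 1176 at an unadjusted p under 0.05. Leaving out any control or TNF array lowered the 111 calls by more than 1.5 times, to 65, 61 and 66 without control 1, 2 and 3 and to 69, 60 and 63 without TNF 1, 2 and 3. Quantile normalization raised the count to 186 (137 higher, 49 lower). Array weights raised it to 221 with less excess of higher calls (116 higher, 105 lower).

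**Figure D1:**
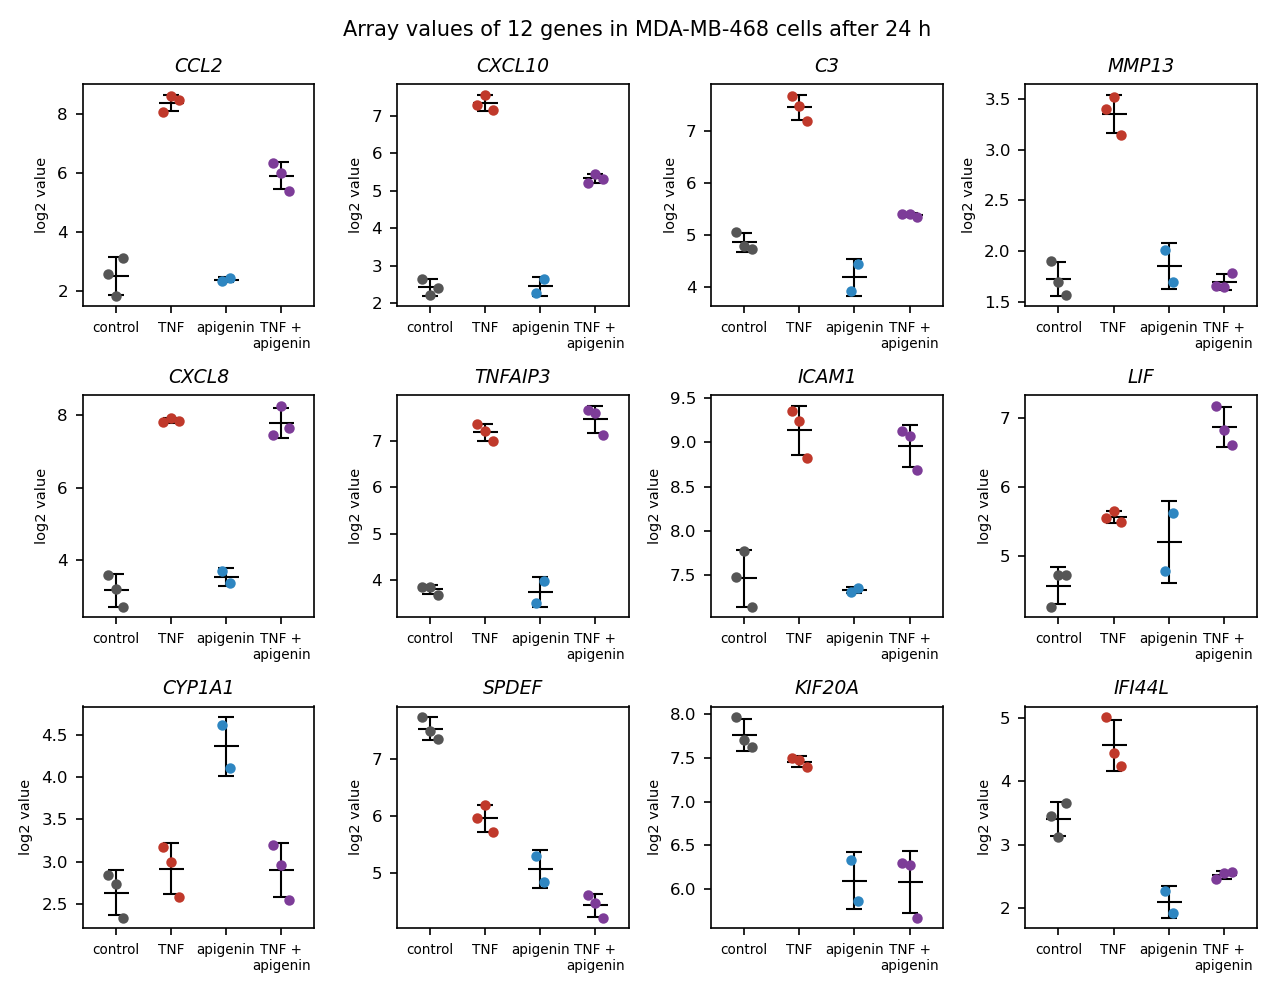
Log2 expression values (vertical axes) of 12 genes on each of the 11 arrays, by treatment group (horizontal axes); points are arrays, short bars are group means and whiskers are 1 SD, with n = 3 for control, TNF and TNF plus apigenin and n = 2 for apigenin. CCL2 averaged 8.39 with TNF and 5.91 with TNF plus apigenin, while CXCL8 averaged 7.86 and 7.79.

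Apigenin alone raised CYP1A1 and CYP1B1, which encode cytochrome P450 enzymes induced through the aryl hydrocarbon receptor. CYP1A1 went from 2.63 ± 0.27 (SD, n = 3) in control to 4.36 ± 0.35 (SD, n = 2), by 1.73 ± 0.25 from a control mean near background (limma adjusted p = 0.00236), and CYP1B1 rose from 6.93 ± 0.15 to 7.9 ± 0.02, by 0.97 ± 0.18 or 1.97-fold (limma adjusted p = 0.0098). Without apigenin 1 both calls were lost, with CYP1A1 at 1.48 (adjusted p = 0.0552) and CYP1B1 at 0.96 (adjusted p = 0.0743). Of the 11 aryl hydrocarbon receptor targets tested these were the 2 called, and adjusted over the list alone 3 rose and 1 fell. The median of the list was -0.12, or 0.06 relative to all genes, its mean 0.12 and camera's direction upward, without a call (adjusted p = 0.062). Fry found change in either direction (adjusted p = 5.6e-07), and its test of movement to either side did not pass (adjusted p = 0.5). Change in either direction was not particular to this list. Fry also found it for macrophage markers and inflammatory cytokines (adjusted p = 0.00019 each) and heat shock genes (adjusted p = 0.0015), though not for ribosomal protein genes (adjusted p = 0.31).

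Genes lower with apigenin alone included SPDEF, which fell by 2.44 on the log2 scale (SE 0.22) or 5.44-fold (adjusted p = 0.000206). PLEKHS1 fell by 2.44 (SE 0.27), S100A7A, of the S100 calcium-binding proteins of skin, by 2.37 (SE 0.27), the amino acid transporter gene SLC6A14 by 2.32 (SE 0.25) and the peptide transporter gene SLC15A2 by 2.22 (SE 0.21). TAF9B fell by 2.19, GBP2, an interferon-induced GTPase, by 2.13, CD14, a receptor for bacterial lipopolysaccharide, by 2.06, CYP4Z1 by 2.03 and CLCA2 by 2.01. Besides CYP1A1, genes that rose included OR4F5 (1.49), CLEC18A (1.45), TRAJ24 (1.44), MINCR (1.22), OR6B3 (1.16), PRM2 (1.05), SPATA31J1 (1.03), NHLH1 (0.99) and GOLGA6L6 (0.98). The calls of GOLGA6L6, SPATA31J1, OR6B3 and TRAJ24 were lost in 10, 8, 7 and 6 of the 11 fits that left out an array, and those of MINCR and NHLH1 in 4. Without apigenin 1 TRAJ24 was at 0.92, OR6B3 at 0.71 and GOLGA6L6 at 0.51. There the calls of OR4F5 (1, adjusted p = 0.147), CLEC18A (1.51, adjusted p = 0.0713), PRM2 (1.14, adjusted p = 0.0639) and CYP4Z1 (-1.89, adjusted p = 0.134) were lost as well, and apart from OR4F5 these kept about their size, with 1 apigenin array left.

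Apigenin alone lowered 14 of 43 G2/M and mitosis genes. The other 29 did not pass, and 31 fell adjusted over the list alone. KIF20A, a kinesin of the dividing midzone, fell by 1.66 (SE 0.23, adjusted p = 0.00146), the kinetochore kinesin gene CENPE by 1.32 (SE 0.26), KIF14 by 1.15 and HMMR by 1.04. Without apigenin 1 the calls of CENPE (-1.08, adjusted p = 0.16), KIF14 (-0.61, adjusted p = 0.391) and HMMR (-0.72, adjusted p = 0.286) were lost, CENPE's also without control 1 and the others' also without control 1 or control 3. The median of the list was -0.69, or -0.52 relative to all genes, and -0.38 after quantile normalization (camera adjusted p = 1.5e-12; adjusted p = 0.64 with an estimated correlation). The 38 G1/S and DNA replication genes had a median of -0.22, or -0.04 relative to all genes, which turned to 0.04 after quantile normalization. Limma called 0 of them, 6 lay below control at an unadjusted p under 0.05, and camera did not call the list (adjusted p = 0.72). Of 10 replication-dependent histone genes, H2BC14 fell by 1.84 (SE 0.37), H2BC9 by 1.23 and the linker histone gene H1-1 by 0.81, and 4 fell adjusted over the list alone. These calls were lost in 2, 3 and 5 of the 11 fits that left out an array, with H2BC9 at -0.66 (adjusted p = 0.373) without apigenin 1. Their median was -0.67, or -0.5 relative to all genes (camera adjusted p = 0.0011; adjusted p = 0.56 with an estimated correlation).

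Apigenin alone lowered 11 of 38 interferon-stimulated genes. The other 27 did not pass, and 22 fell adjusted over the list alone. They included GBP2, SAMD9 (fell by 1.42, SE 0.23), IFI44 (fell by 1.39, SE 0.21) and the apoptosis-linked gene XAF1 (fell by 1.33, SE 0.29; lost in 3 fits with an array left out). The list median was -0.65, or -0.47 relative to all genes (camera adjusted p = 1.3e-09; adjusted p = 0.56 with an estimated correlation). Of 16 FOXO-responsive genes, the transcriptional repressor gene BCL6 fell by 1.14, PDK4, a kinase that restrains pyruvate oxidation, by 1.1 and CITED2 by 1.1, and 8 fell adjusted over the list alone (camera adjusted p = 0.00029; adjusted p = 0.64 with an estimated correlation). Of 14 basal and squamous genes, S100A8 fell by 1.33, S100A9 by 1.29, the keratin gene KRT15 by 1.23 and S100A7 by 1.13, and 8 fell adjusted over the list alone (camera adjusted p = 0.00036; adjusted p = 0.64 with an estimated correlation). Without apigenin 1, which leaves that group with 1 array, the calls of SAMD9 (-1.16), XAF1 (-1.18), BCL6 (-1), PDK4 (-1.17), CITED2 (-0.99), S100A7 (-1.13), S100A8 (-1.28) and S100A9 (-1.07) were lost with changes that moved by less than 1.5 times, and in all PDK4, KRT15 and S100A9 lost theirs in 3, 3 and 4 of the 11 fits.

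Camera called 3 lists as higher relative to other genes although limma called none of their members and their medians lay just below 0, or at 0.11, 0.13 and 0.12 relative to all genes in the order given. The 29 ATF4 and unfolded protein response genes had a median of -0.06 and a mean of 0.02, with 3 above and 1 below control at an unadjusted p under 0.05 (adjusted p = 0.014; adjusted p = 0.91 with an estimated correlation). The 22 long non-coding RNA genes had a median of -0.04 and a mean of 0.03, with 4 above control at an unadjusted p under 0.05 (adjusted p = 0.02; adjusted p = 0.85 with an estimated correlation). The 23 ribosomal protein genes had a median of -0.06 and a mean of 0.03, with 2 above control at an unadjusted p under 0.05 (adjusted p = 0.029; adjusted p = 0.91 with an estimated correlation). After quantile normalization the medians were positive, at 0.24, 0.15 and 0.19. In cells without TNF, CCL2 differed from control by -0.11 ± 0.33 (adjusted p = 0.893), CXCL8 by 0.37 ± 0.27 (adjusted p = 0.482), TNFAIP3 by -0.06 ± 0.22 (adjusted p = 0.915), ICAM1 by -0.13 ± 0.23 (adjusted p = 0.804) and IKBKE by -0.69 ± 0.21 (adjusted p = 0.0903). Of 27 NF-kB targets, TNFAIP2 fell by 0.98 (SE 0.23) and CYLD, a deubiquitinase that restrains NF-kB, by 1.27 (SE 0.3), calls lost in 4 and 3 of the 11 fits that left out an array, and 7 fell adjusted over the list alone (camera adjusted p = 0.53). The list median was -0.21, or -0.03 relative to all genes.

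Apigenin against control gave 35 genes higher and 546 lower by limma, out of 3097 at an unadjusted p under 0.05. The share of calls that were lower was 94%, but 75.5% after quantile normalization (146 higher, 449 lower) and 70.7% after a median shift of each array (148 higher, 357 lower). The count rested on single arrays. It was 84 without apigenin 1, 1290 without apigenin 2, 158 without control 1, 198 without control 3, and 119 with control 2 and apigenin 1 both left out.

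Adding apigenin to TNF lowered part of the TNF-raised genes. CCL2 was 5.91 ± 0.46 (SD, n = 3) with TNF plus apigenin, below its 8.39 with TNF alone by 2.47 on the log2 scale (log2 change -2.47 ± 0.29) or 5.56-fold (adjusted p = 0.000719 by limma). CXCL10 fell by 2.01 (SE 0.18) or 4.02-fold (adjusted p = 8.63e-05), and C3 fell by 2.06 (SE 0.19) or 4.18-fold (adjusted p = 8.63e-05). CXCL8 differed by -0.07 ± 0.24 (95% interval -0.58 to 0.45, adjusted p = 0.968) and TNFAIP3 by 0.28 ± 0.19 (interval -0.13 to 0.69, adjusted p = 0.671). ICAM1 differed by -0.17 ± 0.21 (interval -0.61 to 0.27, adjusted p = 0.844). IKBKE fell by 0.96 (SE 0.19, adjusted p = 0.0216), a call lost in 5 of the 11 fits that left out an array. CYP1A1 lay at 3.17, 2.99 and 2.58 on the TNF arrays and at 3.19, 2.96 and 2.55 on those of TNF plus apigenin. Of the 11 aryl hydrocarbon receptor targets, CYP1A1 and CYP1B1 among them, limma called 0, with 2 higher at an unadjusted p under 0.05.

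Other genes that fell were SLITRK6, a membrane protein of neurons, at 6.12-fold, KMO at 5.72-fold, IL22RA2 at 4.15-fold, IL7R, the interleukin 7 receptor, at 4.07-fold and PLEKHS1 at 3.15-fold. MMP13 fell by 1.67 on the log2 scale (SE 0.17), to 1.69, below the median of the probe sets. Of the 75 genes raised by TNF alone, 69 had a lower estimate with TNF plus apigenin than with TNF, 33 fell by the test, and limma called 0 higher, with 49 lower and 1 higher at an unadjusted p under 0.05. Their median change was -0.79. Which of them count as lowered therefore depends in part on the threshold. Independent lists would share 0.51 genes. The same TNF arrays enter both comparisons, so part of the excess may come from them. Across all genes the changes correlated at -0.242, against -0.5 in 100 simulations of unchanged groups, and the covariance was -0.0215 against a simulated -0.0237, a difference of 0.0022.

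**Figure D2:**
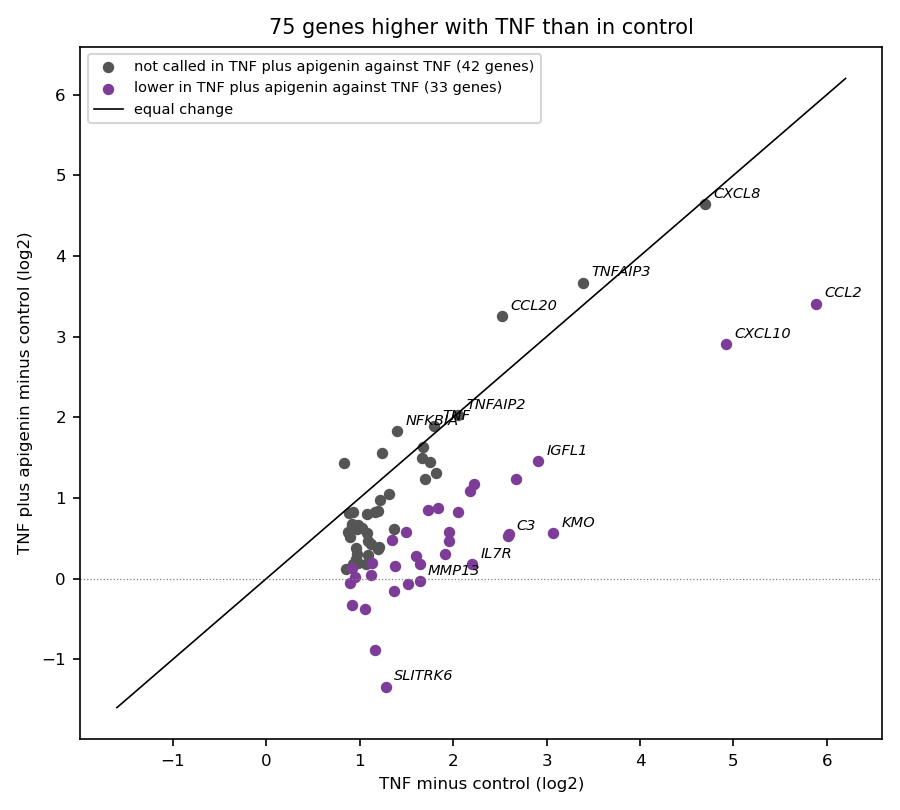
Log2 change against control with TNF (horizontal axis) and with TNF plus apigenin (vertical axis) for the 75 genes that TNF raised, 1 point per gene; the line marks equal change. The 33 genes lower in TNF plus apigenin than in TNF lie under the line, while CXCL8 (4.7 and 4.64) and TNFAIP3 (3.39 and 3.67) lie beside it.

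Genes higher with TNF plus apigenin than with TNF included a transcription factor gene and several non-coding RNA genes. FOSL1, the gene of the AP-1 subunit Fra-1, rose by 1.64 ± 0.25 or 3.11-fold (adjusted p = 0.00383). The antisense transcript HIF1A-AS2 rose by 2.08 ± 0.37 or 4.22-fold (adjusted p = 0.0114; 1.87 and adjusted p = 0.0669 without TNF plus apigenin 2). LINC00880 rose by 1.92 ± 0.2, RASA4B by 1.89 ± 0.31, CFAP43 by 1.74 ± 0.21, LHFPL3-AS2 by 1.73 ± 0.31, FRZB, which encodes a secreted Wnt inhibitor, by 1.69 ± 0.19, IDI2-AS1 by 1.54 ± 0.23, DLGAP1-AS2 by 1.53 ± 0.21 and the carotenoid-cleaving enzyme gene BCO2 by 1.5 ± 0.25. The call of LHFPL3-AS2 was lost in 3 of the 11 fits that left out an array. Of 1005 long non-coding RNA genes tested, 16 rose and limma called 0 lower, with 96 higher and 16 lower at an unadjusted p under 0.05. Of 13230 protein-coding genes, 37 rose and 107 fell. In TNF against control 1 long non-coding RNA gene rose and limma called 0 lower, with 14 higher and 39 lower at an unadjusted p under 0.05.

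In TNF-treated cells apigenin lowered 3 G2/M and mitosis genes and 5 interferon-stimulated genes. Of 43 G2/M and mitosis genes KIF20A fell by 1.37 (SE 0.2, adjusted p = 0.00359), the mitotic kinase gene PLK1 by 0.87 (SE 0.19) and the cyclin gene CCNB1 by 0.77 (SE 0.17), 40 did not pass, and 12 fell adjusted over the list alone. The calls of PLK1 and CCNB1 were each lost in 7 of the 11 fits that left out an array, and those of IFITM1 and IFIT1 in 6 and 4. The list median was -0.37 (camera adjusted p = 7.2e-15; adjusted p = 0.5 with an estimated correlation). Of 38 G1/S and DNA replication genes limma called 0 over all genes and 1 as higher adjusted over the list alone, and 10 lay above TNF at an unadjusted p under 0.05. Their median was 0.28 (camera adjusted p = 0.00028; adjusted p = 0.76 with an estimated correlation). Of 38 interferon-stimulated genes 5 fell, among them IFI44L by 2.04 (SE 0.21), IFI44 by 1.14, IFIT1 by 1.09 and IFITM1 by 0.88, and 15 fell adjusted over the list alone. IFI44L had fallen to 2.52 with TNF plus apigenin, near the median of the probe sets. Camera called the interferon list lower (adjusted p = 7e-14; adjusted p = 0.26 with an estimated correlation).

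**Figure D3:**
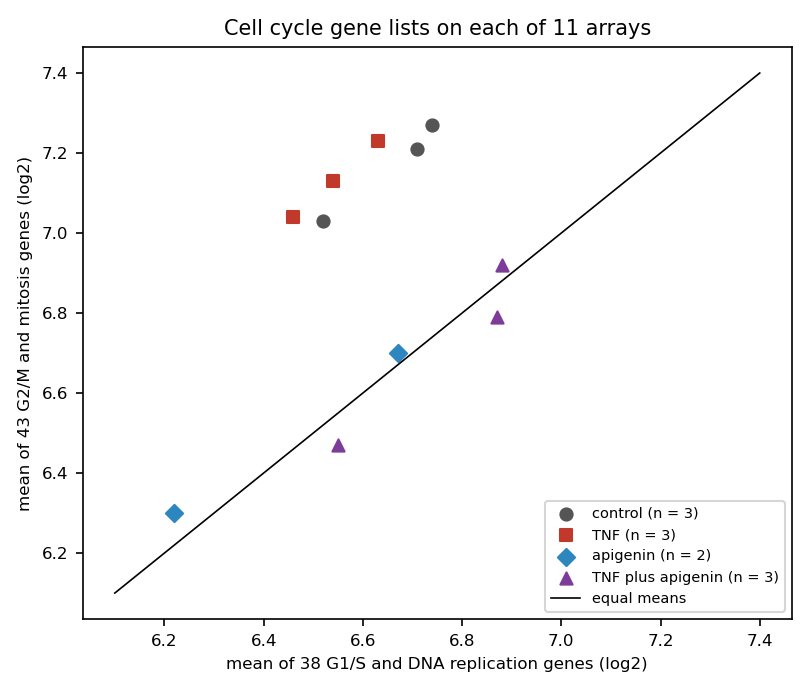
Mean log2 value of 43 G2/M and mitosis genes (vertical axis) against the mean of 38 G1/S and DNA replication genes (horizontal axis), 1 point per array; the line marks equal means. The mitosis mean exceeded the replication mean by between 0.5 and 0.6 on the 6 control and TNF arrays, and the difference lay between -0.08 and 0.07 on the 5 arrays with apigenin.

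Of 23 mesenchymal and matrix remodelling genes 5 fell, MMP13, TNC (fell by 1.6, SE 0.21), the fibronectin gene FN1 (fell by 1.08, SE 0.22), TGFBI (fell by 0.94, SE 0.2) and MMP7 (fell by 0.87), with the calls of TGFBI and FN1 lost in 7 and 5 of the 11 fits that left out an array, and 7 fell adjusted over the list alone (camera adjusted p = 2.7e-07; adjusted p = 0.5 with an estimated correlation). The 16 FOXO-responsive genes had 0 calls by limma over all genes, 6 lower at an unadjusted p under 0.05, and 5 lower adjusted over the list alone (camera adjusted p = 2.4e-05; adjusted p = 0.5 with an estimated correlation). For the 14 basal and squamous genes limma called 0 over all genes, 4 were lower at an unadjusted p under 0.05, and 1 fell adjusted over the list alone (camera adjusted p = 0.0033; adjusted p = 0.6 with an estimated correlation). For the 24 epithelial adhesion genes limma called 0 over all genes, 4 were lower and 1 higher at an unadjusted p under 0.05, and 3 fell adjusted over the list alone (camera adjusted p = 0.0047; adjusted p = 0.76 with an estimated correlation).

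Besides the G1/S list, camera called 4 lists higher than other genes in TNF plus apigenin against TNF, the ribosomal, long non-coding RNA, EGFR and MAPK feedback, and ATF4 lists. Of 23 ribosomal protein genes limma called 0 over all genes and 1 as higher adjusted over the list alone, 7 were higher at an unadjusted p under 0.05, and the median was 0.32 (adjusted p = 4.6e-07; adjusted p = 0.5 with an estimated correlation). Of 22 listed long non-coding RNA genes SNHG5 rose by 0.89 ± 0.19, a call lost in 6 of the 11 fits that left out an array, and 3 rose adjusted over the list alone (adjusted p = 0.0033; adjusted p = 0.6 with an estimated correlation). Of 29 EGFR and MAPK feedback genes FOSL1 and LIF rose, and 3 rose adjusted over the list alone (adjusted p = 0.0064; adjusted p = 0.76 with an estimated correlation). LIF, a cytokine of the interleukin 6 family, rose by 1.3 ± 0.23 or 2.47-fold (adjusted p = 0.0104; 1.15 and adjusted p = 0.0595 without TNF plus apigenin 1). Of 29 ATF4 and unfolded protein response genes CTH, an enzyme of cysteine synthesis, rose by 1.02 ± 0.18, a call lost in 3 such fits, and 2 rose adjusted over the list alone (adjusted p = 0.017; adjusted p = 0.9 with an estimated correlation). The 27 NF-kB targets had 0 calls by limma over all genes and 1 as lower adjusted over the list alone, 3 were lower at an unadjusted p under 0.05, and the median was 0.09, the mean 0.01 and camera's direction downward (adjusted p = 0.97). Of 17 chemokines CCL2 and CXCL10 fell, also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.055).

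TNF plus apigenin against TNF gave 61 genes higher and 108 lower by limma, out of 1766 at an unadjusted p under 0.05. The 169 calls were 90 without TNF 1, 85 without TNF 2, and 98, 91 and 107 without TNF plus apigenin 1, 2 and 3. They rose to 510 after quantile normalization and to 452 after a median shift of each array. The excess of lower calls was not stable, with 59 higher and 48 lower without TNF plus apigenin 3 and 221 higher and 170 lower with array weights.

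Against untreated cells, cells given TNF plus apigenin had high CXCL8 and TNFAIP3 and the lowest SPDEF of the 4 groups. CXCL8 rose 24.9-fold (4.64 ± 0.24, adjusted p = 7.15e-08), TNFAIP3 12.7-fold (3.67 ± 0.19, adjusted p = 7.15e-08), CCL2 by 3.41 ± 0.29 (adjusted p = 1.92e-05), CCL20 by 3.25 ± 0.35 and CXCL10 by 2.91 ± 0.18, these 3 from control means near background. SPDEF fell by 3.07 on the log2 scale (SE 0.2) or 8.42-fold (adjusted p = 4.8e-07), CYP4Z1 by 2.4, S100A7A by 2.32, VTCN1, the immune checkpoint ligand B7-H4, by 2.3 and PLEKHS1 by 2.26. CYP1A1 differed from control by 0.27 ± 0.23 (adjusted p = 0.63) and CYP1B1 by 0.08 ± 0.16 (adjusted p = 0.869).

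Of 27 NF-kB targets 8 rose in that comparison, TNFAIP3, TNFAIP2 (2.03 ± 0.2), TNF (1.89 ± 0.2) and NFKBIA (1.83 ± 0.2) the most, and 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.8e-11; adjusted p = 0.41 with an estimated correlation). Of 17 chemokines 6 rose and CXCL17 fell, a call lost in 3 fits with an array left out, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.9e-06; adjusted p = 0.31 with an estimated correlation). Of 16 cytokines LIF rose 4.92-fold (2.3 ± 0.23) and TNFSF15 rose, while TNFSF10, the death ligand TRAIL, fell by 1.31 (SE 0.18), and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.04; adjusted p = 0.054 after quantile normalization; adjusted p = 0.41 with an estimated correlation). Of 21 NF-kB pathway kinases RIPK2, TRAF3 and IKBKE rose, by 1.12, 0.99 and 0.88, calls lost in 2, 6 and 4 of the 11 fits that left out an array, and 4 rose adjusted over the list alone (camera adjusted p = 0.0039; adjusted p = 0.66 with an estimated correlation). Of 29 EGFR and MAPK feedback genes 4 rose, LIF and FOSL1 (1.99 ± 0.25) the most, FOS fell by 1.33 (SE 0.21), and 6 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0059; adjusted p = 0.66 with an estimated correlation). Of 22 listed long non-coding RNA genes SNHG1, SNHG5 and LUCAT1 rose, by 0.88, 0.86 and 0.86, calls lost in 8, 4 and 4 of those fits, and 7 rose adjusted over the list alone (camera adjusted p = 0.00079; adjusted p = 0.56 with an estimated correlation). Of 23 ribosomal protein genes RPLP1 rose by 1.1 ± 0.25, a call lost in 5 of them, and 2 rose adjusted over the list alone (camera adjusted p = 0.0046; adjusted p = 0.66 with an estimated correlation).

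The combined treatment lowered 6 of 43 G2/M and mitosis genes against control. These were KIF20A (fell by 1.68, SE 0.2), PLK1 (fell by 1.19), CDC20 (fell by 1.04), CCNB1 (fell by 0.98) and 2 others, and 18 fell adjusted over the list alone (camera adjusted p = 3.9e-11; adjusted p = 0.56 with an estimated correlation). Of 14 basal and squamous genes 4 fell, with KRT15 at -1.43 ± 0.21, and 7 fell adjusted over the list alone (camera adjusted p = 5.6e-05; adjusted p = 0.41 with an estimated correlation). Of 24 epithelial adhesion genes the tight junction gene TJP3 fell by 1.29 (SE 0.17) and KRT19 by 0.82, and 3 fell adjusted over the list alone (camera adjusted p = 0.00097; adjusted p = 0.66 with an estimated correlation). Of 10 histone genes H1-1 fell by 0.69, and 2 fell adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.41 with an estimated correlation). Of 16 FOXO-responsive genes BCL6 and PDK4 fell, by 1.05 and 0.91, and 4 fell adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.66 with an estimated correlation). Of 38 interferon-stimulated genes GBP1 rose by 1.23 ± 0.26 and 6 fell, among them IFITM1 by 1.08 and OAS1 by 0.95, and 2 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.022; adjusted p = 0.66 with an estimated correlation). The calls of H1-1, PDK4, KRT19 and GBP1 were lost in 7, 5, 4 and 2 of the 11 fits that left out an array. Among the other genes that fell, those of the basal and squamous genes S100A8 and S100A7 were lost in 6 and 5. That of the interferon-stimulated gene SAMD9 was lost in 5.

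Camera also called the ATF4 list higher in the combined treatment (adjusted p = 0.035; adjusted p = 0.86 with an estimated correlation), with CTH up by 0.87 ± 0.18 and, adjusted over the list alone, 6 up and 1 down. The G1/S list was called higher as well (adjusted p = 0.039; adjusted p = 0.86 with an estimated correlation), with 0 calls by limma and 8 higher and 3 lower at an unadjusted p under 0.05. Of 25 cholesterol and fatty acid synthesis genes FASN, which encodes fatty acid synthase, fell by 1.07 (SE 0.27), SREBF1 by 0.82 and MVK by 0.8, and 4 fell adjusted over the list alone. Camera did not call that list (adjusted p = 0.65), whose median was 0 and mean -0.08. The calls of FASN, SREBF1, MVK and CTH were lost in 6, 5, 4 and 3 of the 11 fits that left out an array. Of 23 mesenchymal and matrix remodelling genes MMP7 and ITGA2 rose, by 0.85 and 0.77, FN1 and TGFBI fell, by 1.14 and 0.97, calls lost in 3, 5, 1 and 4 of those fits, and 6 rose and 3 fell adjusted over the list alone, without a call by camera (adjusted p = 0.23). TNF plus apigenin against control gave 165 genes higher and 282 lower by limma, out of 2529 at an unadjusted p under 0.05. The 447 calls were 211 without control 1, 270 without control 3, 206 without TNF plus apigenin 2 and 258 without TNF plus apigenin 3, and 1233 after quantile normalization. The excess of lower calls turned without TNF plus apigenin 3, with 141 higher and 117 lower.

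In apigenin-treated cells TNF raised CXCL8, TNFAIP3, CCL2, CCL20 and TNFAIP2. CXCL8 rose 19.2-fold (4.26 ± 0.27, adjusted p = 8.63e-07), TNFAIP3 13.3-fold (3.73 ± 0.22, adjusted p = 5.56e-07), TNFAIP2 8.06-fold (3.01 ± 0.23), and, from means near background, CCL2 by 3.51 ± 0.33 (adjusted p = 6.63e-05) and CCL20 by 3.38 ± 0.39. IKBKE rose by 1.56 ± 0.21 (adjusted p = 0.00271) and ICAM1 by 1.63 ± 0.23 (adjusted p = 0.00366; 1.6 and adjusted p = 0.0702 without apigenin 1). Lower with TNF were CYP1A1, which fell by 1.46 (SE 0.25, adjusted p = 0.0146; -1.21 and adjusted p = 0.223 without apigenin 1), CYP1B1, which fell by 0.89 (SE 0.18, adjusted p = 0.0419), OR4F5, PRM2 and CIROZ. The calls of CYP1B1, PRM2, CIROZ, CYP1A1 and OR4F5 were lost in 9, 9, 7, 2 and 1 of the 11 fits that left out an array. Of the 75 genes higher with TNF alone, 31 were also among the 84 higher here, a comparison on separate arrays, where independent lists would share 0.4. The fit gives each gene 1 spread for both comparisons, which can also raise the overlap. Of the 36 lower with TNF alone, limma called 0 lower here, with 4 lower and 2 higher at an unadjusted p under 0.05. Only 7 genes were called lower here in all, and independent lists would share 0.016, so the 0 says little.

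Of 27 NF-kB targets 8 rose with TNF in apigenin-treated cells, CYLD by 2.67 ± 0.3 and NFKBIA by 2.04 ± 0.23 among them, and 17 rose adjusted over the list alone. The list median was 0.65, or 0.49 relative to all genes (camera adjusted p = 2.7e-13; adjusted p = 0.24 with an estimated correlation). Of 17 chemokines 5 rose, with CXCL10 at 2.88 ± 0.2, and 8 rose adjusted over the list alone; the median relative to all genes was 0.51 (camera adjusted p = 5.8e-09; adjusted p = 0.12 with an estimated correlation). Of 38 interferon-stimulated genes GBP1, GBP2, IFIH1 and RIGI rose, by 1.96, 1.61, 1.31 and 1.18, calls lost in 1, 1, 3 and 6 of the 11 fits that left out an array, and 10 rose adjusted over the list alone, with a median relative to all genes of 0.32 (camera adjusted p = 0.0001; adjusted p = 0.61 with an estimated correlation). Of 23 mesenchymal genes MMP7 rose by 1.48 ± 0.19, and 7 rose adjusted over the list alone (camera adjusted p = 0.0061; adjusted p = 0.77 with an estimated correlation). Of 21 NF-kB pathway kinases TRAF3, IKBKE and RIPK2 rose, calls lost in 3, 0 and 9 of those fits, and 3 rose adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.77 with an estimated correlation). Of 20 antigen presentation genes PSMB9, an immunoproteasome subunit, rose by 0.98 ± 0.21, a call lost in 8 of them, and 4 rose adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.77 with an estimated correlation).

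For the 23 growth arrest and p53-responsive genes limma called 0 over all genes and 1 as higher adjusted over the list alone, and 5 were higher at an unadjusted p under 0.05, with a median relative to all genes of 0.15 (camera adjusted p = 0.018; adjusted p = 0.77 with an estimated correlation). For the G1/S list limma called 0, 8 were higher at an unadjusted p under 0.05, and the median relative to all genes was 0.16 (camera adjusted p = 0.014; adjusted p = 0.86 with an estimated correlation). After quantile normalization 4 of these list calls were lost, with adjusted p = 0.43 for G1/S (median 0.06), 0.11 for growth arrest, 0.11 for NF-kB pathway kinases and 0.055 for antigen presentation. TNF plus apigenin against apigenin gave 84 genes higher and 7 lower by limma, out of 2497 at an unadjusted p under 0.05. The share lower was 7.7%, and 18.8% after quantile normalization and 19.5% after a median shift of each array. The 91 calls were 18 without apigenin 1, 598 without apigenin 2, 55 without control 1, 60 without control 3, 59 without TNF 3, and 38, 29 and 153 without TNF plus apigenin 1, 2 and 3.

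The interaction asks whether the TNF effect itself differed with apigenin. CXCL10 had a TNF effect of 4.92 without and 2.88 with apigenin, a difference of -2.03 ± 0.27 (adjusted p = 0.0183), and MMP13 a difference of -1.8 ± 0.26 (adjusted p = 0.0261). Without TNF both genes lay below the median of the probe sets of 2.53, CXCL10 at 2.42 in control and 2.44 with apigenin and MMP13 at 1.72 and 1.85. A fall with apigenin may not be measurable there, and then an equal fall in both backgrounds would give such differences. The median is not a strict floor, as values went down to 0.38, and a floor of these 2 probe sets was not tested. CLCA2, which fell with TNF alone and with apigenin alone, had a difference of 2.12 ± 0.27 (adjusted p = 0.0177), and STAC2, with the same pattern, of 1.52 ± 0.23 (adjusted p = 0.0317). CLCA2 averaged 6.81 in control, 5.03 with TNF, 4.79 with apigenin and 5.14 with both, and STAC2 averaged 4.08, 2.78, 2.84 and 3.06. For CCL2 the difference was -2.37 ± 0.44 (95% interval -3.3 to -1.43), with the same limit, and did not pass (adjusted p = 0.103), nor did that of CYP1A1 at -1.75 ± 0.34 (adjusted p = 0.137) or CYP1B1 at -0.94 ± 0.24 (adjusted p = 0.381). CXCL8 had a difference of -0.44 ± 0.36 (adjusted p = 0.699), TNFAIP3 of 0.34 ± 0.29 (adjusted p = 0.705), IKBKE of -0.27 ± 0.29 (adjusted p = 0.739) and ICAM1 of -0.04 ± 0.31 (adjusted p = 0.964).

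Limma called 2 interactions above 0 and 2 below, out of 1294 at an unadjusted p under 0.05. The calls of CLCA2, CXCL10, MMP13 and STAC2 were lost in 4, 7, 8 and 11 of the 11 fits that left out an array. All were also lost with the replicate number as a block. The count was 0 without control 3, TNF 1, TNF plus apigenin 2 or TNF plus apigenin 3, 1 without TNF 2 or TNF plus apigenin 1, 2 without apigenin 1 and 7 without apigenin 2. After quantile normalization 57.1% of 7 calls were below 0, and after a median shift of each array 70% of 10. Camera called the G1/S list above other genes (median 0.42, or 0.19 relative to all genes; adjusted p = 0.0018; adjusted p = 0.97 with an estimated correlation) and the histone list (median 0.69, or 0.46 relative to all genes; adjusted p = 0.016; adjusted p = 0.97 with an estimated correlation). It called the mesenchymal list below other genes (median 0.04 and mean -0.04, or a median of -0.18 relative to all genes; adjusted p = 0.016; adjusted p = 0.97 with an estimated correlation). After quantile normalization the G1/S call was lost (adjusted p = 0.062). Fry, which tests a list without reference to other genes, called none of these lists to either side (adjusted p = 0.36 for G1/S and histones and 0.85 for mesenchymal genes). By limma 1 member passed in these 3 lists, MMP13, and 7 G1/S genes and 4 histone genes lay above 0 at an unadjusted p under 0.05.

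Effects estimated on separate arrays were related across genes, which are not independent replicates. Over 15865 genes the TNF effects with and without apigenin correlated at 0.355, and the apigenin effects with and without TNF at 0.461. Over the 111 genes called in TNF against control, the slope of the TNF effect with apigenin on that without was 0.587, and 88 of them (79.3%) had the same direction. Over the 581 genes called in apigenin against control, the slope of the apigenin effect with TNF on that without was 0.445, and 529 (91%) had the same direction. The slopes depended on which comparison picked the genes, and were 0.883 over the 91 genes called in TNF plus apigenin against apigenin and 0.998 over the 169 called in TNF plus apigenin against TNF, where the inverse slopes were 0.791 and 0.659. Of the 546 genes lower with apigenin alone, 74 also fell in TNF plus apigenin against TNF, where independent lists would share 3.7. They included SPDEF, KIF20A, PLK1, CCNB1, FN1, VTCN1, the mucin gene MUC1 and the prostaglandin E synthase gene PTGES, of which MUC1 and PTGES were named after their values were seen. Of the 35 genes higher with apigenin alone, 4 also rose there, against 0.13 for independent lists, and these were ADAM20P1, AGBL3, C1orf162 and KLRA1P, likewise named after their values were seen. The comparisons share 1 estimate of each gene's spread, so genes of small spread are more readily called in both. How far this raises such overlaps above those of independent lists was not tested.

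Several lists were called by camera in none of the group comparisons. Of 22 death receptor and apoptosis genes 1 rose in TNF plus apigenin against control, PMAIP1, which encodes the death-promoting protein NOXA, by 1.45 (adjusted p = 0.00175), and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.25). Of 18 NRF2 antioxidant genes AKR1B10 fell in TNF, apigenin and TNF plus apigenin against control, by 1.13, 1.29 and 1.43, calls lost in 5, 2 and 0 of the 11 fits that left out an array. The call with TNF was lost without any 1 of the control and TNF arrays except TNF 2. Adjusted over the list alone, 2 fell with TNF and 2 with apigenin, and 3 rose and 2 fell with both. The heme oxygenase gene HMOX1 of that list rose in TNF plus apigenin against TNF by 0.85 ± 0.18, a call lost in 5 (list camera adjusted p = 0.18, 0.42, 0.73 and 0.45 in these comparisons). It was lost without any 1 of the arrays compared except TNF 3. Of 14 heat shock genes HSPB1, a small heat shock protein, fell by 1.44 with apigenin alone, by 1.01 in TNF plus apigenin against TNF and by 1.7 in TNF plus apigenin against control, calls lost in 1, 4 and 0 of those fits, while 13 did not pass in any of these (camera adjusted p = 0.76, 0.42 and 0.51). Of 28 hypoxia and glycolysis genes the peptide hormone gene ADM rose by 0.94 in TNF plus apigenin against control, a call lost without TNF plus apigenin 2 (camera adjusted p = 0.51). Of the 8 mitochondrially encoded genes limma called 0 in the 5 group comparisons, and 1 was higher in apigenin against control and 1 lower in TNF plus apigenin against apigenin at an unadjusted p under 0.05 (camera adjusted p = 0.1 and 0.12).

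The list medians of markers of other cell types lay near the median of the probe sets, while single markers lay above it. The median level was 2.65 for 10 macrophage markers, with CD68 the highest at 5.32, 2.18 for 9 T and B cell markers, with CD8A the highest at 3.37, 2.11 for 11 fibroblast markers, with COL1A1 the highest at 3.34, and 2.56 for 9 endothelial markers, with KDR the highest at 3.76. Of 7 macrophage markers tested CD14 was lower than control with TNF (fell by 1.22, a call lost in 2 of the 11 fits that left out an array), with apigenin (fell by 2.06) and with both (fell by 1.97), and camera did not call the list (adjusted p = 0.41, 0.72 and 0.63). Of 5 endothelial markers tested CDH5, which encodes VE-cadherin, rose with TNF by 0.92, fell with apigenin by 1.03 and fell in TNF plus apigenin against TNF by 1.25, where 2 members fell adjusted over the list alone (camera adjusted p = 0.0033; adjusted p = 0.41 with an estimated correlation). The first of these calls of CDH5 was lost in 7, the next in 3 and the last in 0 of the 11 fits that left out an array. KDR, a receptor for vascular growth factor, fell with apigenin by 1.32. For 5 fibroblast markers limma called 0 in any comparison and none had an unadjusted p under 0.05. Camera called the fibroblast list lower in TNF plus apigenin against apigenin (median -0.21, or -0.37 relative to all genes; adjusted p = 0.018; adjusted p = 0.24 with an estimated correlation) and in the interaction (median -0.16, or -0.39 relative to all genes; adjusted p = 0.026; adjusted p = 0.6 with an estimated correlation). Both calls were lost after quantile normalization (adjusted p = 0.11 and 0.083). The T and B cell list had 3 tested members, too few for a list test, and their median change lay between -0.08 and 0.11 in the group comparisons.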

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

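The tests of the genes lower with apigenin alone, of the interquartile ranges and of how near CLCA2, STAC2, CXCL10 and MMP13 lay to background were chosen after those results had been seen. The simulated selection, the interactions without apigenin 1 and the splits of the arrays were chosen before their values were known.

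The TNF effect differed with apigenin, by a test of the difference, for 4 genes, and camera placed that difference apart from other genes for 4 lists. The differences were 2.12 for CLCA2, -2.03 for CXCL10, 1.52 for STAC2 and -1.8 for MMP13 on the log2 scale. With the replicate number as a block limma called 0 interactions. Relative to the median of all probe sets, the lowest group mean lay at -0.12 for CXCL10 and at -0.84 for MMP13. A fall with apigenin may therefore be hard to see without TNF, and a floor may account for both differences. For the lists, the camera adjusted p was 0.0018 for G1/S and DNA replication genes, 0.016 for replication-dependent histones, 0.016 for mesenchymal and matrix remodelling genes and 0.026 for fibroblast markers, and none of these held with an estimated correlation or by fry (adjusted p = 0.36 or higher). The calls of G1/S (adjusted p = 0.062) and fibroblast markers (adjusted p = 0.083) were also lost after quantile normalization.

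CLCA2 and STAC2 were lower than control with TNF, with apigenin and with both, and the separate falls did not add up. A floor of the measurement predicts this where a gene lies at background. The lowest group mean of CLCA2 lay 2.26 above the median of all probe sets, which argues against a floor at that median. It cannot exclude a higher background of the CLCA2 probe set itself, as the means with TNF, apigenin and both lay close together. The lowest group mean of STAC2 lay 0.25 above the median, so that for STAC2 a floor may account for the pattern. The dim array apigenin 1 predicts that the interaction goes when that array is left out; it was 2.26 (SE 0.29, adjusted p = 0.0366) for CLCA2 and 1.56 (SE 0.24, adjusted p = 0.138) for STAC2, which argues against that array as the source of either estimate. For CLCA2 a background of its probe set stays open. So does a regulatory step shared by TNF and apigenin, as a hypothesis found and tested on the same data. The call of CLCA2 was lost after quantile normalization (1.79, limma adjusted p = 0.0647), with the replicate number as a block, and in 4 of the 11 fits that left out an array.

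Apigenin alone gave 546 lower genes against 35 higher ones, and array apigenin 1 was dimmer and narrower than the rest. If that array alone made the falls, the same genes should not be lower in TNF plus apigenin against TNF, which uses neither apigenin array. Their median there, after quantile normalization, was -0.47 relative to all genes (95% bootstrap interval over genes -0.51 to -0.44), and 505 of the 546 (92.5%) were lower, which argues against the array as the source of the direction. The interval treats genes as independent, which they are not, and leaves out the spread between arrays. The excess of lower calls stays open, because the share of lower calls was 75.5 percent after quantile normalization, and the number of calls stays open, because it was 84 without apigenin 1. A fall of these genes with apigenin in both backgrounds is therefore a hypothesis about their direction and not about their number.

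Part of the TNF-raised genes, CCL2, CXCL10 and C3 among them, were lower with TNF plus apigenin than with TNF, while CXCL8 and TNFAIP3 did not pass. A narrower range of values on the TNF plus apigenin arrays would lower all strong genes, but the ratio of mean interquartile ranges of TNF plus apigenin over TNF was 1, and 0.98 at the lowest with an array left out. Selection of genes that were high on the TNF arrays by chance was simulated with TNF plus apigenin equal to TNF, and 0 of 100 simulations called as many genes lower, with 1 at the highest against 33 observed. No gene truly differed between these groups in the simulations, so few could pass the adjusted threshold. The simulations also raised a median of 289 genes with TNF, against 75 observed. They therefore cannot decide on selection. The interquartile ranges argue against a narrower range, and apigenin may act on some TNF-raised genes more than on others. This is a hypothesis found and tested on the same data, and a difference in how the cultures of these groups were handled was not tested.

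Of the 10 splits of the control and TNF arrays into groups of 3, 1 gave as many genes as the real one, the real split itself, with 111 calls against 1 in the highest of the other splits. For TNF plus apigenin against TNF 1 of 10 did, with 169 against 7, and for TNF plus apigenin against control 1 of 10 did, with 447 against 0. Splits this few cannot give a share under 0.05.

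Probe sets without a gene of their own, which the comparisons above do not use, also changed, with 21 higher in TNF against control, 38 in apigenin against control, 46 in TNF plus apigenin against TNF, 91 in TNF plus apigenin against control and 24 in TNF plus apigenin against apigenin, out of 15830 tested, and with 4, 80, 16, 43 and 7 lower.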

How the results depend on the processing

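The fits without control 2 and apigenin 1 together, and the slopes over genes called in the other comparison, were chosen after the data had been seen. In the order TNF against control, apigenin against control, TNF plus apigenin against TNF, TNF plus apigenin against control, TNF plus apigenin against apigenin, and interaction, the counts were 111, 581, 169, 447, 91 and 4. With an array left out they ranged from 60 to 128, 84 to 1290, 85 to 197, 206 to 538, 18 to 598 and 0 to 7. The apigenin array left out decided both ends for apigenin against control and for TNF plus apigenin against apigenin. The TNF slope ranged from 0.558 to 0.613 and the apigenin slope from 0.357 to 0.49.

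Counts that moved by more than 1.5 times were as follows, and the cause was not tested except where a stricter threshold lowers a count by construction. Quantile normalization gave 186 for TNF against control, 510 for TNF plus apigenin against TNF, 1233 for TNF plus apigenin against control and 7 interactions. A median shift of each array gave 182, 452, 998 and 10 for the same results. Array weights gave 221, 207, 391, 1197 and 32 for the 5 group comparisons. Leaving out control 2 and apigenin 1 gave 70 for TNF against control, 119 for apigenin against control and 26 for TNF plus apigenin against apigenin. A fit to only the groups compared gave 103 for apigenin against control and 16 for TNF plus apigenin against apigenin. All probe sets without collapse gave 308 for apigenin against control and 1 interaction, counts that include probe sets without a gene of their own; of the gene calls they kept 51, 190, 66, 196 and 31 in the 5 group comparisons and 0 of the 4 interactions, fewer by more than 1.5 times in each. The filter at the 75th percentile gave 137 for TNF plus apigenin against apigenin and 11 interactions, and the trend and robust prior gave 8 interactions. An adjusted p under 0.01 gave 54, 137, 63, 163 and 32 for the 5 group comparisons and, by limma, 0 interactions against 1294 at an unadjusted p under 0.05. A minimum log2 change of 1 gave 299 for apigenin against control and 209 for TNF plus apigenin against control. The TNF slope of 0.587 was 0.533 after a median shift and 0.883 over genes called in the other comparison, and the apigenin slope of 0.445 was 0.998 over genes called in the other comparison. Picking genes on the x axis lowers a slope by construction and picking them on the y axis raises it; the inverse slopes over the latter genes were 0.791 and 0.659.

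With the replicate number as a block the counts were 106, 712, 174, 435, 73 and 0. Whether the numbers pair the arrays stayed unclear. After group means were removed, 15 pairs of arrays that share a number correlated at a median of 0.02 and 30 other pairs at -0.02. The highest correlation was 0.28 among the former, 4 of which lay over 0.1, and 0.19 among the latter. Of the 11 arrays, 6 correlated best with an array of their own number.

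Over all alternatives, 6637 results of named genes stayed on their side of the threshold, 609 lost a call and 214 gained it, and 0 called results of genes or lists changed direction, while 38 that were not called changed sign. For lists 1229 stayed and 204 lost their call, 57 of them with an estimated correlation and 44 by fry. Of 182 called results of named genes, 98 kept their call in all fits that left out an array and 84 lost it in at least 1. Signal over background limits the genes near 2.53, such as CCL2, CXCL10, MMP13 and CCL20 in control.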

Other observations

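The mean effects over both backgrounds, the changes with TNF plus apigenin as shares of those with TNF, and the test of mitosis against replication genes were chosen after the data had been seen.

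Averaged over cells with and without TNF, apigenin raised 157 genes and lowered 872 by limma, 437 of which were called in neither single comparison (625 and 1080 after quantile normalization). MT1F, a metal-binding metallothionein, rose by 1.25 ± 0.2 (adjusted p = 0.00164), and the small nucleolar RNA host gene SNHG19 rose by 1.08 ± 0.19 (adjusted p = 0.00308). Among the lowest were MUC1, a mucin of the epithelial surface, which fell by 1.8 (SE 0.18, adjusted p = 5.76e-05), CP, which encodes the copper-carrying protein ceruloplasmin, by 1.53 (SE 0.13, adjusted p = 3.52e-05), PTGES, a prostaglandin E synthase, by 1.5 (SE 0.18, adjusted p = 0.000191), GNE, the first enzyme of sialic acid synthesis, by 1.41 (SE 0.13, adjusted p = 3.52e-05) and HSD17B2, an enzyme that inactivates oestradiol, by 1.42 (SE 0.13, adjusted p = 3.52e-05). Averaged over cells with and without apigenin, TNF raised 209 genes and lowered 15, 100 of which were called in neither single comparison (312 and 131 after quantile normalization). EDN1, which encodes the vasoconstrictor endothelin 1, rose by 1.79 ± 0.16 (adjusted p = 1.25e-05), OLR1, a scavenger receptor for oxidised lipoprotein, by 2.03 ± 0.16 (adjusted p = 3.46e-06) and ABCC4, an efflux pump, by 1.74 ± 0.13 (adjusted p = 2.43e-06).

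The change against control with TNF plus apigenin was taken as a share of that with TNF alone, on the log2 scale. This was done for 17 genes without a test between them. A change that apigenin made without TNF enters this share, so it is not the part of the TNF response that remained. C3, for example, lay at 3.93 and 4.44 on the apigenin arrays and between 4.73 and 5.06 on the control arrays. The share was 98.6% for CXCL8, 108.3% for TNFAIP3, 98.9% for TNFAIP2, 105.3% for TNF, 89.6% for ICAM1, 130.8% for NFKBIA and 128.8% for CCL20. It was 59.2% for CXCL10, 57.9% for CCL2, 29.6% for the acute phase gene SAA1, 23.7% for complement factor gene CFB, 20.3% for C3, 18.1% for KMO, 16.4% for TNC, 8.1% for IL7R and -1.8% for MMP13. For LIF it was 230.8%, of a TNF change of 1 that limma did not call. The shares of CXCL10, CCL2, MMP13 and CCL20 start from control means of 2.42, 2.51, 1.72 and 2.62, at or near background, so they depend on it and do not rank beside those of the other genes. After quantile normalization the changes in TNF plus apigenin against TNF kept their size, with CCL2 at -2.53 (adjusted p = 0.00119), C3 at -2.09 (adjusted p = 8.62e-05), CXCL8 at -0.04 (adjusted p = 0.96) and TNFAIP3 at 0.3 (adjusted p = 0.282).

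Mitosis genes were lower relative to replication genes on every array with apigenin, and a shift in the cell cycle that goes with apigenin is a candidate explanation. The mean of 43 G2/M and mitosis genes minus the mean of 38 G1/S and DNA replication genes differed by -0.55 between the 5 arrays with apigenin and the 6 without (two-sided exact permutation test over 462 splits, p = 0.0022, the smallest it can give). Without TNF the difference was -0.46 and with TNF -0.63, and after quantile normalization it was again -0.55. For the mitosis genes alone it was -0.52 (exact permutation p = 0.0022), with -0.67 without and -0.4 with TNF. For the replication genes alone it was 0.04 (exact permutation p = 0.76), with -0.21 without and 0.23 with TNF. The value without TNF rested on the dim array apigenin 1. The mean of the replication genes was 6.22 there, against 6.67 on apigenin 2 and between 6.52 and 6.74 on the control arrays. The score cancels a shift of a whole array but cannot tell fewer cells in mitosis from lower transcription of mitosis genes in the same cells, and cell cycle phases were not analysed here. The lists were fixed in advance, but their difference was picked after the list results were known, so this is a hypothesis.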
